A study of Mus musculus with 8 samples.

How the data were processed

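Liver cells of 8 C57BL/6 mice were profiled by bulk RNA sequencing. All mice lacked Ifih1, the gene of the double-stranded RNA sensor MDA5, and carried Alb-Cre, a recombinase expressed in hepatocytes. They differed in Adar, the gene of the RNA-editing enzyme ADAR1: 3 mice had wild-type alleles (wt/wt), 2 had 1 floxed allele (wt/flox) and 3 had floxed alleles on both chromosomes (flox/flox). The series' design text counts 2 flox/flox mice, whereas 3 samples bear that genotype and all 3 were used. Per the labels' protocols, livers were perfused with collagenase, the cells were pelleted at low speed, red cells were lysed and live cells were taken from a Percoll gradient, so the material is enriched for hepatocytes. Also per the labels' protocols, ribosomal RNA was depleted and the libraries were strand-specific.

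The deposited values are raw read counts per gene symbol, with reads on the gene's strand and reads on the opposite strand in separate columns, per the file headers. The submitters' processing notes name the genome build GRCm38 (mm10) and the program DESeq2. The aligner, the counting program and the gene annotation are not given in the sources used here. Each file holds 1 library. Reads that aligned to several places were tallied apart by the authors, as the deposited counts show, so genes with near-identical copies are under-counted and are marked as uncertain where named. Each file has 25229 genes and 5 further rows that name no gene, which were left out of library sizes and tests. Of the sense reads given to a gene, to no gene or to several genes, those in no gene made up 22.2% to 40.0% and ambiguous reads 0.317% to 0.668%. Alignments to several places, when added to that total, made up 9.0% to 10.9% in wt/wt and 3.9% to 5.0% in the other groups.

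Sense counts were analysed. Sense gene reads per library ranged from 75875711 to 132303735. A count of 0 allows up to 3 reads at a confidence level of 95%, and such limits cover counting error only. No pair of libraries agreed within sampling noise. The files name 25229 symbols, of which 24704 (97.9%) were matched to GENCODE M21 on GRCm38 for coordinates and exon length. No mitochondrially encoded mRNA of the list written for them is in the files.

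The genes were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with TMM size factors, the filterByExpr filter on the groups, and Benjamini-Hochberg adjustment at 0.05, two-sided. The filter left 14728 genes. All 8 libraries entered a single fit with genotype and labelled sex as terms, and 3 contrasts were taken from it. Normalised values are CPM, counts scaled here by TMM-adjusted library sizes. Fold changes are those of the fit, which adjusts for the labelled sex, and can differ from the ratio of the group means. Gene lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 for lists with at least 5 tested members, and 37 of the 38 lists could be tested. Members of a list were counted at an adjusted p over all genes and also adjusted over the list alone.

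The groups, the tests, the covariate, the lists, the first alternatives and the rule for named genes were fixed before the data were examined. By that rule Adar, Ifih1, Grn and Egfr are always named. For each contrast the rule adds the 8 higher and the 8 lower genes of largest fold change among those past the threshold, with a mean CPM of at least 5 in the higher group and no overlap between the groups' libraries. Predicted genes, Rik clones and small RNAs named Mir, Snor, Rn7 or n-R are passed over. It also adds up to 4 called members of each list with the smallest adjusted p, or 1 or 2 members with the smallest p where none was called.

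The alternatives chosen in advance were RLE and upper-quartile size factors, no filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, no sex term, the replicate number as a block with and without the sex term, only the 2 groups compared, each library left out, and camera with an estimated correlation. Alternatives added after seeing the data took the sex from Xist and Y-linked transcripts, left out the 2 libraries whose transcripts contradict the labelled sex, removed a trend with exon length, added antisense to sense counts, or used library size alone. An uncalled result that stayed uncalled was counted as not changed by an alternative. The scripts were tested on simulated counts for 14728 genes with the means, dispersions and library sizes of these data, with 200 genes changed. In flox/flox against wt/wt, 0% of genes changed by 1.5-fold, 12.1% of those changed by 2-fold and 67.8% of those changed by 4-fold were recovered, with 7 false calls among 14528 unchanged genes. The corresponding shares were 0%, 1.7% and 54.2% with 5 false calls in flox/flox against wt/flox, and 0%, 9.3% and 60.8% with 2 false calls in wt/flox against wt/wt.

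The names of the deposited tables mark the wt/wt libraries apart from all others, which carry the mark of a second batch. Genotype and this batch cannot be told apart in either contrast with wt/wt. The wt/flox and flox/flox libraries share a mark. Each replicate number also stands for an age (11, 9 and 7 weeks for numbers 1, 2 and 3).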

Results

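The transcriptomes of hepatocyte-enriched liver cells were measured in 3 wt/wt, 2 wt/flox and 3 flox/flox mice, all lacking Ifih1. The design asks how loss of Adar1 in hepatocytes changes expression when MDA5 is absent, and the series title names progranulin (Grn) and the epidermal growth factor receptor (Egfr). Sense gene reads numbered 82967317, 103970706 and 95095456 in wt/wt, 96405090 and 75875711 in wt/flox, and 98337152, 130823166 and 132303735 in flox/flox, each in the order of the replicate numbers. Reads in no gene averaged 25.8% ± 3.2 (SD, n = 3), 34.5% ± 3.98 (n = 2) and 36.7% ± 2.89 (n = 3) of sense reads in these groups.

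Reads of Adar (chromosome 3, 89715022 to 89753446, GRCm38) were not lower in the flox/flox libraries. Its level was 37.2 ± 14.2 CPM in wt/wt (SD, n = 3), 26.9 ± 6.93 in wt/flox (n = 2) and 42.4 ± 6.74 in flox/flox (n = 3). The fitted log2 fold change was 0.04 (SE 0.19) for flox/flox against wt/wt, 0.24 (SE 0.24) against wt/flox, and -0.21 (SE 0.22) for wt/flox against wt/wt. The edgeR adjusted p was 0.899, 0.917 and 0.559. Counts over the whole gene include exons outside any floxed part, and the floxed exons are not stated in the labels, so this total checks the genotype labels little. Ifih1 had 0 to 4 reads in each library.

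The sex labels were checked by Xist, the RNA that coats the inactive X chromosome, and 4 Y-linked genes. Both sets followed the label in 6 libraries. The library labelled flox/flox replicate 1 is labelled female but had 31 Xist reads and 21255 Y-linked reads. The library labelled flox/flox replicate 2 is labelled male but had 246646 Xist reads and 0 Y-linked reads. The fixed model uses the labelled sex, so every contrast below carries this contradiction, and some results are also given for an alternative, added after seeing the data, that takes the sex from the transcripts. In a principal component analysis the first component (39.7% of variance) separated libraries by these transcripts, and the second (27.3%) separated wt/wt from the other libraries.

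**Figure D1:**
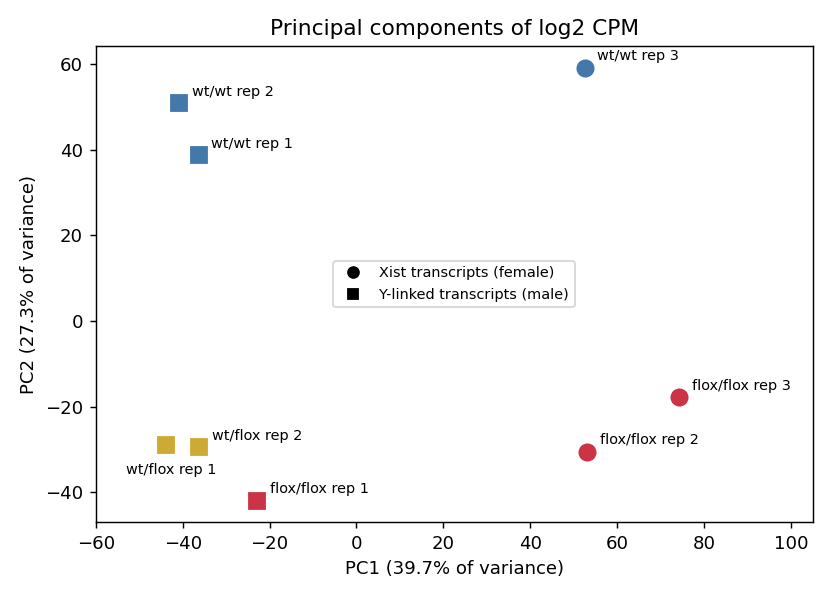
Principal components of log2 CPM over the tested genes, with 1 point per library (blue wt/wt, yellow wt/flox, red flox/flox; circles Xist transcripts, squares Y-linked transcripts). PC1 (39.7% of variance) parts circles from squares, and PC2 (27.3%) parts wt/wt, at 38.6 and above, from the other libraries, at -17.7 and below.

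The main contrast set flox/flox against wt/wt. Genes of bile acid transport and drug metabolism were among those that rose in flox/flox, and markers of sinusoidal endothelial cells and macrophages were among those that fell. Of 14728 genes, 1810 rose and 1845 fell. The nuclear long noncoding RNA Neat1 (chromosome 19, 5824708 to 5845478) rose 5.92-fold, from 379.2 ± 191 to 2308 ± 714 CPM (SD, n = 3 each; edgeR adjusted p = 0.0132). Lipg, which encodes endothelial lipase, rose 3.68-fold from 14.1 ± 2.42 to 58.1 ± 30.5 CPM. Col4a5, a basement membrane collagen, rose 4.05-fold, the organic anion transporter gene Slco1a4 3.59-fold and Pls1, which encodes an actin-bundling protein, 3.59-fold. Cyp3a59 rose 4.1-fold but belongs to a family of near-identical genes and is uncertain. Gpr52 (3.57-fold) and D17H6S56E-5 (5.99-fold) also rose and were not matched to the annotation.

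Among the genes that fell, Rpph1, the RNA component of RNase P (chromosome 14, 50807449 to 50807767), dropped 6.31-fold from 2275 ± 422 to 383.2 ± 106 CPM (edgeR adjusted p = 0.00399). Cox5b, a subunit of cytochrome c oxidase (chromosome 1, 36691449 to 36693681), fell 4.37-fold from 66.3 ± 3.9 to 15.0 ± 0.452 CPM (edgeR adjusted p = 0.00331). Atp5k, a subunit of ATP synthase, fell 5.38-fold, Mrpl52, of the mitochondrial ribosome, 4.26-fold, and Scarna13, a small Cajal body RNA, 4.52-fold. Rpl36a (4.07-fold), Fam25c (4.07-fold) and the histone gene H4c1 (4.78-fold) fell as well and are uncertain, since near-identical copies exist.

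Of the 4 genes named in advance, Grn was 212.4 ± 19.4 CPM in flox/flox and 138.2 ± 53 in wt/wt (log2 fold change 0.56, SE 0.23, edgeR adjusted p = 0.115). Egfr was 1281 ± 1010 in flox/flox and 1008 ± 341 in wt/wt (log2 fold change 0.24, SE 0.65, adjusted p = 0.809). By library Egfr was 2437.9 CPM in flox/flox replicate 1, which is labelled female but has Y-linked transcripts. It was 854.0 and 550.6 in flox/flox replicates 2 and 3, which have Xist transcripts, and 1400.5, 778.3 and 845.9 in wt/wt. The fit with the labelled sex does not follow this split in flox/flox, so its estimate for Egfr rests on the contradicted labels. Neither Grn nor Egfr passed the threshold in any of the 3 contrasts of that fit. The list of the progranulin and EGFR pathway had 7 members that rose and 1 that fell of 30 (the same counts adjusted over the list alone). Lrig1, a negative regulator of EGFR, rose 1.8-fold, the sheddase gene Adam17 1.69-fold and Tnfrsf1a 1.45-fold, while the adaptor gene Grb2 fell 1.53-fold. The camera adjusted p of this list was 0.0372, and the adjusted p was 0.781 with an estimated correlation.

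**Figure D2:**
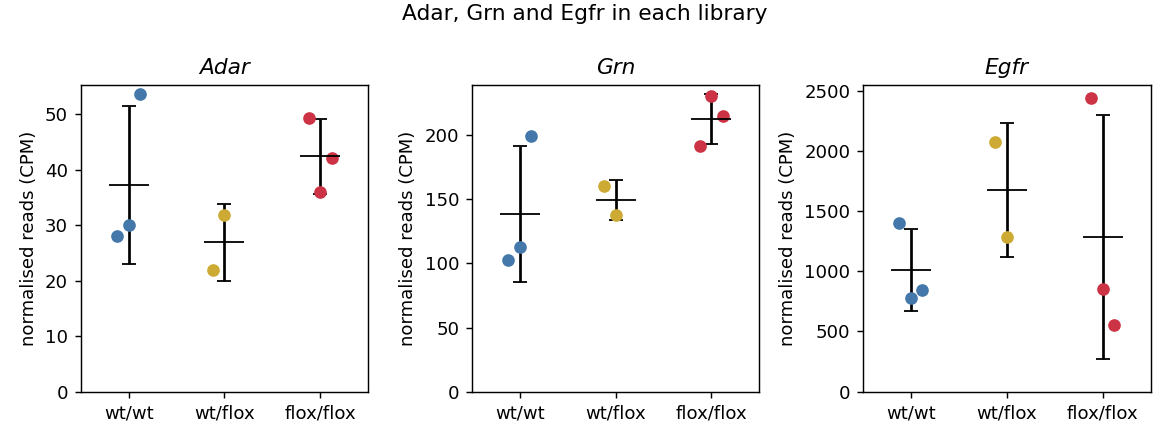
Normalised reads (CPM) of Adar, Grn and Egfr, with 1 point per library and the group mean ± SD as bars (n = 3, 2 and 3). Adar in flox/flox (42.4 ± 6.74) lies within the range of wt/wt, Grn was 212.4 ± 19.4 in flox/flox against 138.2 ± 53 in wt/wt, and Egfr varied most in flox/flox (1281 ± 1010).

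Hepatocyte pathways moved in several lists. In bile acid synthesis and transport 12 of 24 genes rose and 0 fell, both over all genes and adjusted over the list alone. The canalicular conjugate pump gene Abcc2 rose 2.81-fold from 446.3 ± 80.3 to 1288 ± 138 CPM, the sterol transporter gene Abcg5 3.1-fold, Abcc3 2.33-fold and the phospholipid transporter gene Abcb4 2.14-fold. Of 30 cytochrome P450 genes of drug metabolism 12 rose and 1 fell, among them Cyp2a12 (1.68-fold), Cyp2d22 (1.62-fold), Cyp2c23 (1.72-fold) and Cyp4f15 (1.86-fold), with the same counts adjusted over the list alone, and these families share similar sequences. Of 29 acute phase genes 7 rose, the same count as adjusted over the list alone, including Cp, which encodes ceruloplasmin (2.04-fold), Cfb (1.66-fold) and Serpina3n (1.77-fold). Of 32 proliferation genes 9 rose (12 rose and 1 fell adjusted over the list alone), with Ccna2 at 3.45 ± 0.783 against 1.12 ± 0.431 CPM and Cenpf at 3.79 ± 1.44 against 0.873 ± 0.617. The camera adjusted p was 0.000469 for bile acids, 0.000139 for the cytochromes, 0.0243 for acute phase genes and 0.000139 for proliferation. With an estimated correlation the adjusted p was 0.781, 0.781, 0.884 and 0.884.

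Markers of several other liver cell types were lower in flox/flox. Of 20 sinusoidal endothelial markers 9 fell (13 adjusted over the list alone) and 0 rose, with Ehd3 3.06-fold lower (11.3 ± 2.32 against 33.7 ± 7.12 CPM), Eng 2.8-fold, Dnase1l3 2.38-fold and Flt4 2.35-fold. Of 17 Kupffer cell markers 9 fell (14 adjusted over the list alone), among them Cd163 (3.06-fold), C1qc (4.21-fold) and C1qa (3.48-fold), while the iron exporter gene Slc40a1, which hepatocytes also express, rose 2.21-fold. Of 24 monocyte and recruited macrophage markers 8 fell, such as Lyz2 (2.63-fold) and Tyrobp (3.91-fold), and of 8 genes of MHC class II presentation 6 fell, such as Cd74 (3.48-fold) and H2-Ab1 (3.59-fold). Of 15 replication-dependent histone genes 7 fell, led by H2bc4 (2.89-fold), H4c8, H1f4 and H4c4, which have near-identical copies. The neutrophil list had 3 falls of 9, the T and NK list 1 of 17 (Ccl5) and the stellate list 1 of 18 (Hand2). Several of these genes were at low levels, with S100a8 at 1.05 ± 1.62 CPM, Ccl5 at 0.220 ± 0.252 and Hand2 at 0.583 ± 0.29 in wt/wt. Adjusted over the list alone, 10 monocyte, 6 MHC class II, 9 histone, 4 neutrophil, 0 T and NK and 0 stellate genes fell. The camera adjusted p was 6.36e-06 for endothelial, 2.88e-05 for Kupffer, 0.000139 for monocyte, 2.7e-05 for MHC class II, 2.21e-05 for histone, 0.0116 for neutrophil, 0.00888 for T and NK and 0.0121 for stellate genes. With an estimated correlation the adjusted p was 0.884, 0.884, 0.781, 0.781, 0.781, 0.884, 0.884 and 0.9. Camera did not call the cholangiocyte (adjusted p = 0.388), B and plasma cell (0.37) or erythroid and platelet lists (0.972). Of 12 cholangiocyte markers 2 rose, Pkhd1 (3.18-fold) and Atp1b1 (2.46-fold), and 0 fell, with a median log2 fold change of 0.62.

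Markers of immune cells were higher in wt/wt replicate 3 than in the other wt/wt libraries by a median of 1.95 on the log2 scale for Kupffer, 2.18 for monocyte, 3.91 for neutrophil and 1.65 for T and NK genes, and Clec4f stood at 62.8 CPM against 14.0 and 13.5. Without that library camera no longer called the neutrophil (adjusted p = 0.579) or T and NK lists (0.105), nor did it without flox/flox replicate 1 (0.0784 and 0.0786). The median log2 fold change of the neutrophil markers was -1.68 with all libraries, -0.84 without wt/wt replicate 3 and -1.47 without flox/flox replicate 1, and that of the T and NK cell markers was -1.35, -1.04 and -1.18. The progranulin and EGFR list was not called without wt/wt replicate 3 (0.0566), flox/flox replicate 1 (0.0762) or flox/flox replicate 3 (0.0786). Of the 14 lists called in this contrast, 7 stayed called in the same direction whichever library was left out (MHC class II, Kupffer, monocyte, endothelial, histone, cytochrome P450 and bile acid genes), and 7 did not. The acute phase list, for example, was not called without wt/wt replicate 2 (0.109) or flox/flox replicate 2 (0.296), nor the proliferation list without flox/flox replicate 2 (0.132). Leaving out libraries does not test the sex term. Without that term camera called 5 lists higher and 2 lower, against 5 and 9 with it, so not all lower lists that stayed called above were kept. Relative to the mean over libraries, Kupffer markers averaged -0.045, -0.129 and 1.824 on the log2 scale in wt/wt and -0.24, -0.753 and 0.795 in flox/flox. Endothelial markers averaged 0.572, 0.387 and 0.978 against -0.847, -0.283 and 0.206.

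With the sex by transcripts fewer Kupffer, monocyte, MHC class II and neutrophil genes were called in this contrast (3, 4, 3 and 2 fell). The T and NK list had 1 fall, and 2 B and plasma cell genes fell, against 0 with the labelled sex, without a list call (adjusted p = 0.43). In that fit 14 endothelial and 9 histone genes fell. The camera adjusted p was 0.0329 for Kupffer, 0.0499 for monocyte, 0.0329 for MHC class II, 0.107 for neutrophil, 1.77e-12 for endothelial and 1.04e-07 for histone genes. With an estimated correlation the adjusted p was 0.708 for endothelial and 0.684 for histone genes and 0.922 for the others.

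Of 46 interferon-stimulated genes 3 fell, Isg15 (3.6-fold), Ifi35 (1.73-fold) and Irf7 (1.85-fold), and 0 fell adjusted over the list alone. The camera adjusted p was 0.0449, and the adjusted p was 0.9 with an estimated correlation. This call depended on single libraries. Isg15 was 4.13, 5.48 and 39.4 CPM in the wt/wt libraries and 5.90, 2.62 and 5.51 in the flox/flox libraries, and Irf7 was 13.6, 18.3 and 112.2 against 57.5, 11.0 and 37.9. Without wt/wt replicate 3 the direction of the list turned (camera adjusted p = 0.439), without flox/flox replicate 1 or 3 it was not called (0.123 and 0.301), and with the sex by transcripts the adjusted p was 0.91. Usp18, an interferon-stimulated negative regulator singled out after its values were seen, was 67.0, 11.5 and 35.7 CPM in the flox/flox libraries against 7.77, 8.27 and 45.7 in wt/wt.

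Other lists held single changes without a list call. Of 22 genes of MHC class I presentation 2 rose and 5 fell, with the immunoproteasome genes Psmb8 (2.1-fold) and Psmb9 (2.11-fold) lower and the trimming peptidase gene Erap1 2.04-fold higher. Of 26 hepatocyte identity genes 4 rose and 1 fell (0 and 1 adjusted over the list alone), the fall being the fatty acid binding gene Fabp1 (3.98-fold). Of 23 pericentral genes 5 rose and 1 fell, Glul (2.08-fold). Of 27 genes of the urea cycle and amino acid catabolism 1 rose, Cps1 (1.76-fold), and 5 fell, such as Ass1 (2.47-fold). Of 26 genes of gluconeogenesis and glycolysis 2 rose, such as the glucose transporter gene Slc2a2 (2.28-fold), and 7 fell, such as Gapdh (1.82-fold). In all, camera called 14 of 37 lists (5 higher, 9 lower), 0 with an estimated correlation and 7 without the sex term.

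**Figure D3:**
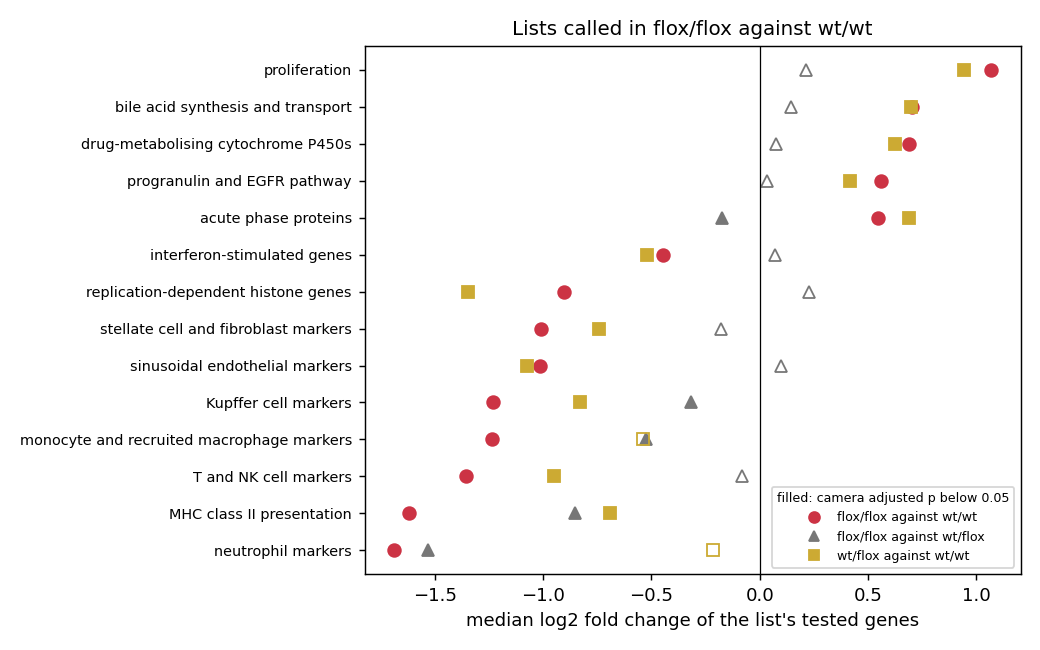
Median log2 fold change of the tested members of each list that camera called in flox/flox against wt/wt, for the 3 contrasts (red circles, grey triangles and yellow squares), with filled symbols where the camera adjusted p was below 0.05. Medians against wt/wt lie on the same side in flox/flox and wt/flox, such as 0.70 and 0.70 for bile acid genes and -1.01 and -1.07 for endothelial markers.

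Fold changes in this contrast also varied with exon length. The median log2 fold change was 0.89 for 322 genes under 500 bases, -0.49 for 397 genes of at least 500 but under 1000 bases, -0.42 for 1736 genes of at least 1000 but under 2000 bases and 0.31 for 2410 genes of 8000 bases or more.

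**Figure D4:**
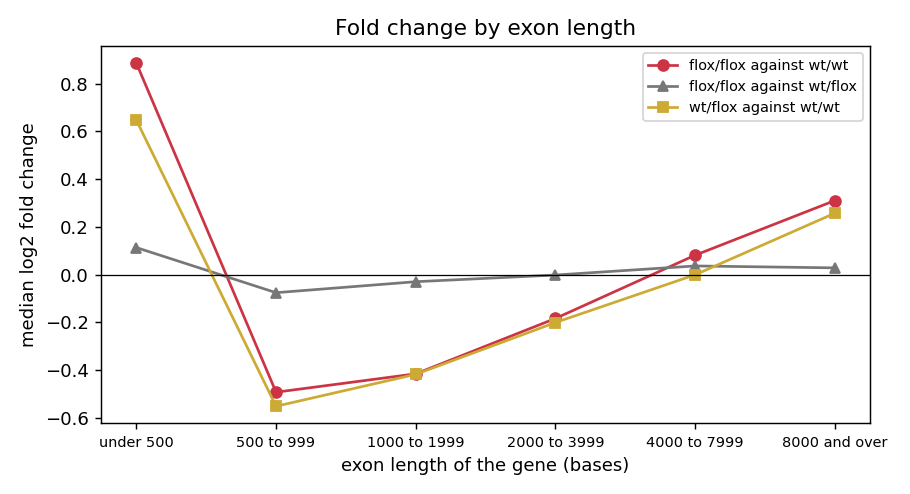
Median log2 fold change of the tested genes by exon length in bases for the 3 contrasts. Both contrasts with wt/wt start at 0.89 (flox/flox) and 0.65 (wt/flox) under 500 bases and pass from -0.42 at 1000 bases or more but under 2000 to 0.31 (flox/flox) and 0.26 (wt/flox) at 8000 or more, while flox/flox against wt/flox starts at 0.11 and passes from -0.03 to 0.03.

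The gene count against wt/wt depended on single libraries. edgeR called 3655 genes with all libraries, 0 without flox/flox replicate 2 (3693 at an unadjusted p under 0.05), 378 without wt/wt replicate 3, 1116 without wt/wt replicate 2, 2235 without wt/wt replicate 1 and 1054 without the 2 libraries of contradicted sex, a fit in which flox/flox keeps 1 library. The fit without flox/flox replicate 2 keeps only flox/flox libraries labelled female, although replicate 1 has Y-linked transcripts. With the sex by transcripts edgeR called 4282, of which 3352 were among the 3655. All wt/wt libraries carry another batch mark than all flox/flox libraries, so genotype and batch cannot be separated here.

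The contrast of flox/flox against wt/flox asks what loss of the second allele adds, and its libraries share a batch mark. edgeR called 0 of 14728 genes, with 581 genes (3.94%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.917. limma-voom called 0 and DESeq2 34. The smallest adjusted p of DESeq2 belonged to Gadd45g (1.17e-07), with a log2 fold change of -3.52. Its calls also included Hmgcs1 (adjusted p = 0.00468), Hes1 (0.000818), Txnip (0.00219) and Chac1 (0.0388). Among them too were Cyp2b13 (7.19e-05), Sult3a1 (3.05e-05) and Cyp2b9 (0.0499), which are known for female-biased expression in mouse liver, and all of these were singled out after their values were seen. Without flox/flox replicate 1 edgeR called 7 genes, the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty as well as Col4a3, Etfbkmt and Pls1, and without both libraries of contradicted sex it called 1, Ctse, all named after their values were seen. The lowest p in the interferon list belonged to Samd9l, with 55.2 ± 12.3 CPM in flox/flox (n = 3) and 17.8 ± 3.48 in wt/flox (n = 2), log2 fold change 0.93 (SE 0.27, edgeR adjusted p = 0.917). Hmgcs1, of cholesterol synthesis, was 940.9 ± 288 against 382.7 ± 96.1 CPM (log2 fold change 1.49, SE 0.30, edgeR adjusted p = 0.917).

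Camera called 10 lists in this contrast, 2 higher (female-biased liver genes and cholesterol synthesis) and 8 lower (MHC class II, neutrophil, male-biased, monocyte, gluconeogenesis, acute phase, Kupffer and integrated stress genes), though 0 of their members were called over all genes. Adjusted over the list alone, 4 MHC class II genes and 1 neutrophil gene fell and 1 cholesterol gene rose. Their camera adjusted p was 6.7e-07, 3.92e-06, 2.74e-06, 3.92e-06, 0.00018, 0.00149, 0.00861, 0.00861, 0.0184 and 0.0482 in that order. With an estimated correlation the adjusted p was 0.891 for each. With the sex by transcripts 6 lists were called: interferon-stimulated genes (adjusted p = 2.52e-09), MHC class I (0.0315) and female-biased genes (0.0226) higher, and male-biased (0.000229), neutrophil (0.0027) and endothelial genes (0.0226) lower. With an estimated correlation the adjusted p of each was 0.916. In that fit 0 interferon-stimulated genes were called singly, and their median log2 fold change was 0.94. It was 0.07 in the model with the labelled sex (camera adjusted p = 0.3), so the call on interferon genes within the batch depends on which sex is assigned to the 2 flox/flox libraries. The median log2 fold change of the female-biased list was 7.08 with the labelled sex and 0.31 with the sex by transcripts. That of the male-biased list was -1.03 and -0.32. By the transcripts flox/flox includes female libraries and wt/flox does not, so the size of these changes also depends on the sex assigned. Other lists turned as well. Without the sex term the Kupffer (adjusted p = 0.00434) and monocyte lists (0.0104) were called higher. Without flox/flox replicate 2 the female-biased (0.000839) and male-biased lists (9.36e-09) were called in the opposite direction, and the cholesterol list turned without a call (0.884). The flox/flox libraries left in that fit are all labelled female, so the sex term is estimated within wt/wt alone. It is then applied to flox/flox replicate 1, which has Y-linked transcripts. Of the 10 lists only MHC class II stayed called in the same direction whichever library was left out. Even so, that list turned without the sex term (camera adjusted p = 0.871) and was not called with the sex by transcripts (0.331).

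The contrast of wt/flox against wt/wt asks what loss of 1 allele does, again across batch marks. Of 14728 genes 635 rose and 665 fell. Neat1 rose 12.7-fold, from 379.2 ± 191 CPM (n = 3) to 4462 ± 1010 (n = 2; edgeR adjusted p = 0.0257). The stress-inducible gene Gadd45g rose 9.58-fold, Steap4, a metalloreductase gene, 4.4-fold and the cationic amino acid transporter gene Slc7a2 3.7-fold. Zyg11a (4.27-fold), Srrm4 (4.1-fold), Apbb3 (3.8-fold) and Gpr52 (4.34-fold) rose too. Hmgcs1 fell 4.6-fold from 1626 ± 111 to 382.7 ± 96.1 CPM (edgeR adjusted p = 0.0236). G0s2, an inhibitor of lipolysis, fell 6.06-fold, Rpph1 5.81-fold, the transcriptional regulator genes Id3 and Hes1 4.47-fold and 4.3-fold, Scarna13 3.82-fold, Atp5k 3.81-fold and Cotl1 3.68-fold.

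Several lists of the main contrast were called here too. Of 24 bile acid genes 7 rose, with Abcc2 2.78-fold, Abcg8 3.25-fold and Abcg5 2.84-fold higher, and of 30 cytochrome P450 genes 5 rose, such as Cyp1a2 (1.76-fold), and 8 each adjusted over the list alone, where 1 cytochrome gene fell. Of 29 acute phase genes 2 rose, Steap4 and Cp (2.01-fold), and 10 adjusted over the list alone. Of 15 histone genes 7 fell (10 adjusted over the list alone), and of 20 endothelial markers 2 fell, Ehd3 (2.78-fold) and Dnase1l3 (2.71-fold), and 16 adjusted over the list alone. Of 24 cholesterol synthesis genes 4 fell, as adjusted over the list alone, among them Hmgcs1, Fdps (2.01-fold) and Nsdhl (1.8-fold), without a list call (camera adjusted p = 0.0767). Of 23 pericentral genes 2 rose and 2 fell (5 and 3 adjusted over the list alone), without a list call (camera adjusted p = 0.94). The falls were Axin2 (3.07-fold) and Glul (2.73-fold). Camera called 13 of 37 lists, 6 higher (acute phase, cytochrome P450, bile acid, proliferation, progranulin and EGFR, and male-biased genes) and 7 lower (histone, endothelial, Kupffer, interferon-stimulated, MHC class II, T and NK, and stellate genes), with adjusted p from 5.98e-09 (histone) to 0.0423 (stellate). No single member of the proliferation, Kupffer, interferon-stimulated, MHC class II, T and NK, stellate or male-biased lists was called with the labelled sex. With an estimated correlation 0 were called, at adjusted p from 0.813 for histone genes to 0.997 for stellate genes. With the sex by transcripts 12 proliferation, 12 cytochrome P450 and 2 male-biased genes rose, and 10 endothelial and 2 monocyte genes fell. In that fit the MHC class II (adjusted p = 0.0861), stellate (0.0578) and male-biased lists (0.0687) were not called, while the monocyte list was called lower (0.0271). The adjusted p of the monocyte list was 0.988 with an estimated correlation. Of the 13 lists called with the labelled sex, 7 stayed called in the same direction whichever library was left out, and the interferon-stimulated, MHC class II, proliferation, T and NK, stellate and male-biased lists did not.

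This count was fragile as well. edgeR called 1300 genes with all libraries, but 0 without any single one of wt/wt replicates 1, 2 and 3, wt/flox replicates 1 and 2 or flox/flox replicate 2 (2698 to 3957 at an unadjusted p under 0.05). It called 2913 without flox/flox replicate 1, 2132 with the sex by transcripts, 2699 without the 2 libraries of contradicted sex and 0 with a length offset (3610 at an unadjusted p under 0.05), which removes each library's trend with exon length. DESeq2 called 2774. The upper-quartile factors gave 565 higher and 1062 lower genes, and the median log2 difference of all genes stood at -0.129 with them against -0.053 with TMM. With library size alone it stood at -0.401 (224 higher, 2597 lower), and in the main contrast at -0.318 against 0.008 with TMM (513 higher, 3943 lower).

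The genes changed in the same direction against both controls, wt/wt and wt/flox, numbered 0, since edgeR called 0 against wt/flox (8 by DESeq2, 0 by limma-voom). The fold changes of these contrasts had a correlation of 0.457 across genes and a covariance of 0.285. In 20 simulations of unchanged groups that share the flox/flox libraries, these were 0.52 and 0.149, so the observed correlation was lower and the observed covariance higher (by 0.136) than in the simulations. Between flox/flox and wt/flox, each against wt/wt, 1199 genes were called in the same direction (576 higher, 623 lower) and 0 in opposite directions. Independent lists would share 78 and 83.3. The simulations with shared wt/wt libraries gave at most 0 shared calls. They changed no gene and so could hardly share a call, and they do not measure how many shared calls the shared controls can give. The correlation was 0.544 (simulated 0.289) and the covariance 0.360 (simulated 0.0741). With 3 wt/wt libraries the controls could not be split into parts of at least 2, so part of the excess may come from the shared controls, and the batch mark is shared as well.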

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

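The tests of gene length, batch and allele number were all chosen after the results were seen, and the counts of sample splits were chosen before.

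Reads in no gene stood above the wt/wt level in both other groups, and reads on the opposite strand in flox/flox alone. Sense reads in no gene made up 34.46% in wt/flox and 36.73% in flox/flox, against 25.84% ± 3.2 in wt/wt (SD, n = 3). Reads on the opposite strand made up 7.648% of gene reads in flox/flox, against 7.352% ± 0.171 in wt/wt and 6.812% in wt/flox. None of these differences was tested.

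Fold changes against wt/wt varied with exon length, in a pattern shared by wt/flox and flox/flox, which were set against the same wt/wt libraries. Across genes the correlation of log2 fold change with log10 exon length was weak, at 0.096 in flox/flox and 0.104 in wt/flox. In flox/flox against wt/wt, 640 genes with 8000 or more exon bases rose and 72 fell, whereas 73 genes of at least 1000 but under 2000 bases rose and 501 fell, and under 500 bases 60 rose and 25 fell. A length bias between libraries predicts that other short genes fall as well. The first test of this went the other way, since 690 genes under 1000 bases outside the ribosomal protein and respiratory chain classes had a median log2 fold change of 0.163. A second test, tried because of that result, took the 266 protein-coding genes among them and gave -0.794, while the 424 others had a median of 0.779, so a length bias may apply to protein-coding genes but the pair of tests leaves it open overall. If a length trend were the whole cause of the fall of both classes, the length offset would bring their median near 0. That median stayed at -0.762 (SE 0.042, from the spread over genes and not between mice). The offset cannot decide this, since it pools short protein-coding genes with other short genes that moved the opposite way. An equal effect of each Adar1 allele lost predicts equal steps in length slope. The step to flox/flox minus that to wt/flox was -0.203 (SE 0.033). Only the step to wt/flox crosses the batch mark, so this difference cannot decide on the allele effect. The slopes of flox/flox and wt/flox differed by 0.013 (SE 0.019), as a difference between library batches predicts, but genotype and batch mark cannot be told apart here, and an effect already complete with 1 allele lost stays open and untested.

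The count of changed genes was set against other splits of the 6 wt/wt and flox/flox libraries. With the sex term 1 of 9 splits, the real one, gave as many genes (3655, highest other 110), and 1 further split could not be fitted. Without the sex term it was 1 of 10 (4400, highest other 113). For gene lists 5 of 9 splits gave as many as the real 14 (highest other 18). Without the sex term each of the 9 other splits called more lists (12 to 19) than the real one (7), and the cause of this was not tested. The splits are too few for a share under 0.05, and the real split is also the split by batch mark.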

How the results depend on the processing

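The alternatives on transcript-based sex, the 2 libraries of contradicted sex, exon length, antisense reads and library size alone were chosen after the data were seen. The cause of the changes below was not tested, apart from the smaller number of libraries where some were left out. Where a group kept 1 library, it was assumed to vary like the others. Alternatives for normalised values did not apply to counts.

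For flox/flox against wt/wt edgeR called 3655 genes, 1054 without the 2 libraries of contradicted sex and 0 to 5238 when each library was left out. For flox/flox against wt/flox the count of 0 became 34 with DESeq2, 1 without those 2 libraries and 0 to 7 when each library was left out. The genes changed the same way against both controls numbered 8, 1 and 0 to 7 in these settings. For wt/flox against wt/wt the count of 1300 became 2774 with DESeq2, 2847 with only the 2 groups compared, 2132 with the sex by transcripts, 2699 without those 2 libraries, 0 with the length offset, 770 with the length offset and the sex by transcripts, 2821 with library size alone and 0 to 2913 when each library was left out. Of the genes changed against both controls, the 7 without flox/flox replicate 1 included the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty. Adar was not called in any contrast under any alternative.

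Replicate numbers were not used to pair the libraries in the main fit. Of 7 same-numbered pairs 3 correlated above 0.1 (0.012 to 0.451), and 4 of 8 libraries correlated best with their own number. These values do not settle whether the numbers pair the libraries. The highest, between wt/wt replicate 3 and flox/flox replicate 3, also joins libraries with Xist transcripts. Each number stands for an age, so the replicate block is also a block by age. With the replicate block and the sex term kept, 4364, 5 and 1807 genes were called in flox/flox against wt/wt, flox/flox against wt/flox and wt/flox against wt/wt. Against both controls 5 were called, the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty, which were lower, and Col4a3, which was higher. In that fit the labelled sex and the block of number 3 differ only in flox/flox replicate 1. That library therefore adds nothing to the estimated group differences. With the replicate block in place of the sex term the counts were 4794, 0 and 1439, and with the replicate block and the sex by transcripts 1786, 0 and 0. In this last fit flox/flox replicate 2 adds nothing, for the same reason.

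Camera's 14, 10 and 13 lists in the same order of contrasts became 0, 0 and 0 with an estimated correlation. Without the sex term 7 were called in flox/flox against wt/wt, and with the sex by transcripts, with or without the length offset, 6 in flox/flox against wt/flox. Leaving out each library gave 12 to 16, 9 to 14 and 11 to 17.

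Some directions reversed. In flox/flox against wt/wt the log2 fold change of Irf7 was 0.053 with the replicate block in place of the sex term, 0.564 with the replicate block and the sex by transcripts and 0.230 with the length offset and the sex by transcripts, and that of Psat1 was 0.078 with the replicate block and the sex by transcripts. The interferon-stimulated list turned higher, with an adjusted p of 0.91 without the sex term and 0.986 with the length offset and the sex by transcripts, and its adjusted p spanned 8.04e-10 to 0.439 when each library was left out. In flox/flox against wt/flox, without the sex term, the adjusted p of reversed lists was 0.871 for MHC class II, 0.00434 for Kupffer and 0.0104 for monocyte genes. With the sex by transcripts it was 0.999 for Kupffer and 0.763 for monocyte genes, and with the length offset added 0.821 and 0.553. The male-biased list reversed without the 2 libraries of contradicted sex (0.865). Leaving out flox/flox replicate 2 reversed the cholesterol (0.884), female-biased (0.000839) and male-biased lists (9.36e-09). When each library was left out, the adjusted p of the cholesterol list spanned 7.39e-12 to 0.884, that of the female-biased list 7.24e-34 to 0.00114 and that of the male-biased list 6.8e-28 to 0.0158. Changes of 1.5-fold were not recovered in the simulated counts, in which far fewer genes were changed than edgeR called in flox/flox against wt/wt. In that real contrast smaller fitted changes were called, such as Tnfrsf1a (1.45-fold, edgeR adjusted p = 0.0154) and Asgr2 (1.37-fold, 0.0344). The simulation therefore does not give the smallest change that could be called there.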

Other observations

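The ribosomal protein and respiratory chain lists, and all tests of sex and of wt/wt replicate 3, were chosen after the results were seen.

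Genes of cytosolic ribosomes and of the respiratory chain were lower in both groups with floxed alleles than in wt/wt. Of 82 ribosomal protein genes 79 fell in flox/flox against wt/wt, with a median log2 fold change of -1.19, and 43 fell in wt/flox against wt/wt, with a median of -0.82. Of 77 respiratory chain subunit genes 66 and 46 fell, with medians of -0.90 and -0.71. The camera p in flox/flox against wt/wt was 1.4e-39 and 4.64e-30, and the p was 0.0911 and 0.0864 with an estimated correlation. In wt/flox against wt/wt the camera p was 2.62e-28 and 3.43e-25, and the p was 0.137 and 0.106 with an estimated correlation. In flox/flox against wt/flox, which share a batch mark, edgeR called 0 members of either list, but the medians lay below 0, at -0.32 (SE 0.026) and -0.17 (SE 0.024). The SE of medians in this paragraph come from the spread over genes, taken as independent. They do not measure the spread between mice. The camera p there was 5.37e-18 and 1.11e-08, and the p was 0.221 and 0.326 with an estimated correlation. With the length offset 61 and 45 genes fell in flox/flox against wt/wt, and the medians were -0.93 (SE 0.049) and -0.57 (SE 0.065). In wt/flox against wt/wt it left 0 and 0 calls, where edgeR called 0 genes in all, but the medians stayed below 0 at -0.58 (SE 0.043) and -0.35 (SE 0.052). Many ribosomal protein genes have processed pseudogenes that share reads with them, and the share of alignments to several places also differed between wt/wt and the other groups, so these levels are uncertain.

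The sex transcripts of 2 flox/flox libraries contradicted their labels. The tables argue against a mixture of male and female cells, since the transcripts of the other sex stood at no more than 0.0179% of their level in libraries of that sex. Genes with sex-biased liver expression sided with the transcripts in 2 of the 2 libraries, so these transcripts do not stand alone, but this does not tell how the mismatch arose. A sex recorded wrongly, an exchange of these libraries and another mislabelling all stay open. Whether the library labelled flox/flox replicate 1 belongs to wt/flox stays open. Its distance to wt/flox was 1.169 times that to the other flox/flox libraries, which by the bound set for this test would speak against it, but the single distances overlapped (0.934 and 1.001 to wt/flox, 0.958 and 0.698 to flox/flox) and removing the sex also removes part of the genotype difference, so that verdict was withdrawn after the value was seen.

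Interferon-stimulated genes were higher in wt/wt replicate 3 than in the other wt/wt libraries by a median of 2.37 on the log2 scale (SE 0.249), Kupffer cell markers by 1.95 (SE 0.213) and neutrophil markers by 3.91 (SE 0.639). This library is also the female and the youngest of its group, and sex and age were not tested as explanations. A lower share of hepatocytes, with the other cells in unchanged proportions, predicts a like rise in the markers of every other cell type. Cholangiocyte markers differed by 0.04 (SE 0.215), endothelial markers by 0.55 (SE 0.097) and stellate markers by 0.65 (SE 0.111). These lie apart from the Kupffer markers by more than their SE, so the marker lists did not rise alike in this library. The SE here come from the spread over the genes of a list, taken as independent, and do not measure variation between preparations. The bound set for that test was 0 or lower, which 0.04 missed, so the test as set gives no verdict. A lower share of hepatocytes together with a changed mix of the other cells stays open, since endothelial and stellate markers rose too. Interferon-stimulated genes exceeded Kupffer markers by 0.422, which leaves open whether Kupffer cells could be the only source of these transcripts.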
